A study of Homo sapiens with 12 samples.

How the data were processed

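Peak lists of 12 ChIP-seq libraries from Huh7 cells were used, 1 for each of FLAG, H2A.Z, H2A.Zac, H3K27ac, H3K4me1 and input in cells with lentiviral VPS72 and in cells with an empty vector. Groups were taken from the sample titles, which name the virus of the control lenti-HA. The genotype labels of the overexpression libraries name VPS72 for the input and a running series of other VPS names for the rest, which the titles and the design text do not, and they were read as VPS72. Peak names of the control H3K4me1 library spell H3k3me1, and its title and antibody label were followed.

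Peaks were called with MACS2 separately for each library, per the submitters' processing notes and the peak names, and the notes also name FastQC, Trimmomatic and BWA, without versions. The control used for calling and the thresholds are not given in the sources used here. The deposited fold of a peak is the ratio of its summit to the local background of the peak caller, with the same constant added to both, so it depends on depth. The deposited p and q are −log10 values at the summit, and the authors' integer score is derived from the −log10 p per the format of the peak caller. The deposited summit offset is a position within the peak. The smallest deposited −log10 p of a list was 1.30 to 1.31, so the lists had been kept at a p of 0.05 and not on q. The second deposited list of each library held the same summits in 12 of 12 libraries and added nothing. The p and q were used only to describe, rank or filter peaks within a list. Folds were also set side by side between conditions at the strongest regions, as description only.

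The submitters' processing notes name both hg19 and hg38. All peaks on 23 of 23 chromosomes lay within hg19 lengths, and on 15 of 23 some lay past the last gene of GRCh38, so coordinates are given as hg19, 1-based. Chromosome lengths came from GenomeInfoDb 1.38.1 and cytogenetic bands from circlize 0.4.16. The only annotation used here was a gene table of another build, GRCh38.p14, and coordinates were not converted. For this reason the planned promoter gains and losses, promoter occupancy of the 12 gene lists, location of regions relative to genes, peaks over the VPS72 gene and motifs at summits were not run. No result is given for any of the gene lists, which covered SREBP1 lipogenesis, cholesterol synthesis, mTORC1, the ATF3 stress response, the SRCAP and TIP60 machinery, fatty acid oxidation, hepatocyte identity, the cell cycle, immediate early genes, housekeeping genes, developmental genes and markers of other cell types. Their members were fixed before the data were examined.

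Peaks on chromosomes 1 to 22 and X were joined into regions where they overlapped, which left every list at its deposited length. Region numbers, the percentage of regions overlapping by at least 1 bp, and covered length were compared side by side, with no test between conditions. Overlap was set beside that of 100 random placements on the same chromosome, of at most 10000 regions each. Intervals are Wilson 95% intervals. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

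Whole reads at each summit were recovered from the deposited fold and −log10 p under the formula and Poisson model of MACS2, with a tolerance of 0.002 on the −log10 scale, relative to −log10 p where that is above 1. At least 99.979% of the peaks of each ChIP library gave a whole number of reads at the fitted scale. The median share over all scales tried was at most 3.50%, on a sample of up to 400 peaks per library, so the 2 figures are not like for like. Depth followed from the lowest background, the shortest peak and an assumed genome size of 2.7 Gb. It came to 4.38, 17.9, 21.7, 21.3 and 22.6 M (mega) reads in the control and 3.07, 20.4, 25.02, 23.8 and 21.8 M with overexpression, for FLAG, H2A.Z, H2A.Zac, H3K27ac and H3K4me1. The background of the scaled libraries gave 18.8 and 20.2 M (mega) reads for the inputs. Another genome size would change all depths by the same factor. Heights were compared at regions with a q of 0.05 or less in one library that overlapped any deposited region of the other, with the highest summit there. Summit height is the number of reads at the summit over the genome average of the library, and local background is that of the peak caller over the same average. Read recovery was tested on simulated data with 4 settings and 5198 peaks, of which 100% were recovered, and the overlap function on 20000 simulated regions. As a further calculation, reads were placed at random over 50 Mb at each library's depth. Their numbers were multiplied by the fitted scale, rounded down and called at a p of 0.05, with gaps of 0, 50 or 150 bp closed between calls. For H3K4me1, the overexpression reads at each summit were thinned at random, 20 times, to the genome average of the control, and the mean number of regions past a limit was taken; this was added after the data were seen.

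Local background was taken as the median over histone peaks in bins of 500 kb with at least 50 peaks in each condition. A bin was called raised at 2 times the genome average in both conditions, a limit set after the profile was seen, and its parts of 50 kb with at least 3 peaks at 1.5 times. Bins within 2 Mb of a centromere band were also summarised apart, and bins raised in 1 condition whatever the other showed.

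Alternative settings, fixed before the data were examined, were a q of 1e-05 or less, a fold of at least 5, every deposited line, leaving out regions in an input, covered length, a reciprocal overlap of 50%, the summit inside the other region, and equal numbers of regions. A q of 0.05 or less, at least 3 or at least 10 reads, and, for H2A.Z and H3K4me1, further limits on reads and heights were added after the data were seen. The named-genes rule, fixed beforehand, covered named genes, the 6 strongest FLAG regions per condition and the 6 strongest input peaks per input. Its gene parts could not be run, apart from naming the bands of VPS72, ATF3, MTOR and SREBF1, which are background knowledge. The strongest histone regions and those of 1 condition were added after the data were seen. Peaks on unplaced contigs and the decoy sequence were left out of all region counts.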

Results

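VPS72, also called YL1, is the subunit of the SRCAP and TIP60 complexes that binds the histone variant H2A.Z. The series asks what gains of VPS72 do in liver cancer cells, and its title ties them to lipid synthesis through ATF3, mTORC1 and SREBP1. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done in Huh7, a hepatocellular carcinoma line, after a FLAG tag had been knocked in at the end of the VPS72 coding sequence. Cells infected for 24 h with lentivirus carrying VPS72-FLAG were compared with cells infected with an empty vector (lenti-HA virus in the sample titles), the control. Each condition had 1 library each for FLAG, H2A.Z, acetylated H2A.Z (H2A.Zac), H3K27ac, H3K4me1 and input, which makes 12 libraries in all. The FLAG tag sat on the endogenous VPS72 in the control, and on both that and the lentiviral protein with overexpression. FLAG ChIP of cells without a tag was not analysed here, so nonspecific FLAG signal could not be separated from VPS72 binding, and a FLAG region need not be a VPS72 binding site.

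The deposited values were peak lists in hg19 coordinates, and regions were counted on chromosomes 1 to 22 and X. With 1 library per group, no difference between conditions had a replicate check, and none was tested. Percentages carry Wilson 95% confidence intervals, which cover counting error only. Peak folds, p and q are the authors' values. Folds set side by side between conditions are description only, as a fold depends on the depth of its library. The lists had been kept at a p of 0.05, so counts are also given for regions with a q of 0.05 or less, a choice made after the lists were seen. Depth was recovered from the deposited fold and p of each peak, at an assumed genome size of 2.7 Gb. It was 4.38 M (mega) reads for FLAG in the control and 3.07 M with overexpression, and 17.9 to 25.02 M for the histone libraries. No spike-in or other scale between libraries was analysed here, so a summit height is relative to the genome average of its own library. "Found in both" is used of regions with a q of 0.05 or less in the selecting library and any deposited peak in the other.

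FLAG was strongest at the same places in both conditions. Strongest, here and below, means the highest −log10 q and not the highest fold, which for control FLAG was 30.8. The control had its strongest FLAG peak at 1q42.13 (chromosome 1, 228744006 to 228746968), the band of the 5S ribosomal RNA genes, with a fold of 19.7 there and of 20.2 with overexpression. The 21p11.2 region (chromosome 21, 9825453 to 9827490) had folds of 8.80 and 10.0, and the 2p22.3 region (chromosome 2, 33141191 to 33141900) had folds of 11.5 and 12.04. A pair of neighbouring regions at 7p11.2 (chromosome 7, 56438036 to 56440824 and 56441022 to 56442510) had folds of 9.28 and 9.39 in the control and 8.76 and 8.48 with overexpression. These 5 places were among the 6 strongest in each condition, and the region at 21p11.2 also overlapped an input peak. All but 1 of the 6 strongest control regions overlapped a deposited peak of at least 1 histone mark.

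The control FLAG list held 184114 regions and the overexpression list 551907, a ratio of 3.00. At a q of 0.05 or less the order was the other way round, with 68395 regions in the control and 46307 with overexpression, a ratio of 0.677. The overexpression FLAG library had 0.69988 times the depth of the control one, and a limit on q does not allow for depth. A true fall in FLAG regions therefore cannot be told apart from the shallower library. Of the deposited overexpression peaks, 297013 (53.8%) had 1 read at their summit, and no control FLAG peak had so few. Of the control FLAG regions with a q of 0.05 or less, 40.2% (39.9 to 40.6%) overlapped such a region with overexpression, against 2.97% for randomly placed regions. Conversely, 61.4% (61.0 to 61.9%) of the overexpression regions were found in the control. At FLAG regions found in both, the median summit height over the genome average, overexpression over control, was 0.865 when the control list selected the regions and 1.11 when the overexpression list did. The strongest control region without any overexpression peak lay at 20q13.33 (chromosome 20, 60176322 to 60177231; 31 reads), and the strongest in the other direction at 5q11.2 (chromosome 5, 50975292 to 50975838; 19 reads). Regions present in 1 condition, and histone regions named from here on, were chosen after their values were seen.

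**Figure D1:**
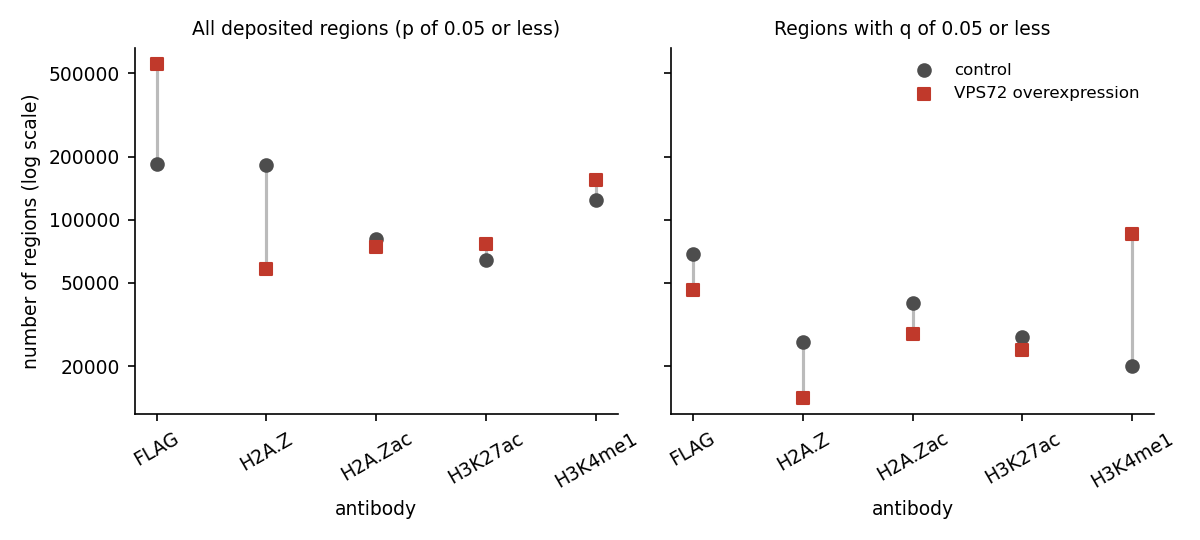
Number of regions (log scale) for each antibody in the control (circles) and with VPS72 overexpression (squares), 1 library each, for all deposited regions (left) and for those with a q of 0.05 or less (right). FLAG goes from 184114 to 551907 regions on the left and from 68395 to 46307 on the right, while H3K4me1 is higher with overexpression in both panels.

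**Figure D2:**
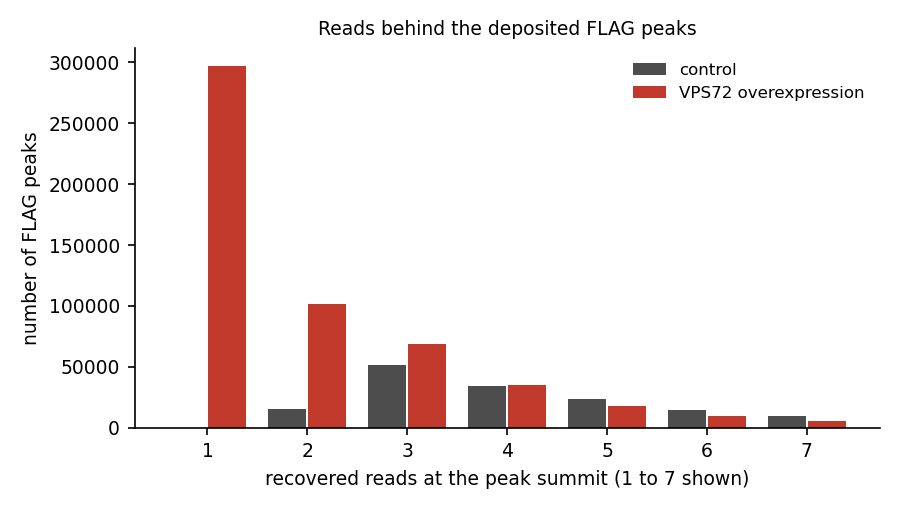
Number of deposited FLAG peaks by recovered reads at the summit, from 1 to 7, in the control (grey) and with VPS72 overexpression (red). The 297013 overexpression peaks with 1 read have no counterpart in the control.

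H2A.Z, the variant that VPS72 binds, had fewer regions with overexpression. The lists held 182213 regions in the control and 57951 with overexpression, a ratio of 0.318, and 26099 and 14109 with a q of 0.05 or less, a ratio of 0.541. The strongest control H2A.Z region lay at 2q13 (chromosome 2, 114340719 to 114342170), with a fold of 11.1 in the control and 6.80 with overexpression. The next, at Xq23 (chromosome X, 115003337 to 115005383), had folds of 6.82 and 5.95. The other 4 of the 6 strongest lay on 11q12 and 11q13. All 6 had the lower fold with overexpression, but 5 of the 6 strongest overexpression regions had the higher fold there, so the direction went with the list that selected the regions. Of the control regions with a q of 0.05 or less, 37.3% (36.7 to 37.8%) overlapped such a region with overexpression, and 71.4% (70.7 to 72.1%) of those with overexpression were found in the control. At H2A.Z regions found in both, the median height ratio was 0.852 by the control list and 0.993 by the overexpression list. Counts of regions with at least 10 reads gave a ratio of 1.11, whereas with at least 10 times the genome average it was 0.534. Limits on height are relative to depth but fall on whole reads, so they cut each library at a different height. The overexpression H2A.Z library was 1.14 times as deep as the control one.

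The acetylated marks had lower summits over the genome average with overexpression at the places that both conditions shared. Less of the mark and a less enriched library cannot be told apart here. At H2A.Zac regions found in both, the median height ratio was 0.652 whichever library selected them, and 4.48% of the 29648 regions selected in the control were higher with overexpression. For H3K27ac, a mark of active promoters and enhancers, the ratios were 0.748 and 0.757, and 12.7% of 23120 regions were higher. The strongest control H2A.Zac regions were at Xq23 (chromosome X, 115003444 to 115005469), with folds of 18.6 and 13.9, and at 2q13 (chromosome 2, 114340817 to 114342278), with 30.1 and 19.7. The strongest H3K27ac region of both lists by q, at 14q12 (chromosome 14, 31675120 to 31678196), had folds of 31.0 and 22.2. The highest H3K27ac folds, at other regions, were 42.4 in the control and 37.6 with overexpression. Of the 6 strongest regions selected with overexpression, 1 for each of these marks had the higher fold there. Region numbers differed less as deposited and at a q of 0.05 or less, but not at every stricter limit. At a q of 1e-05 or less the H2A.Zac ratio was 0.626. H2A.Zac had 81287 regions in the control and 74204 with overexpression as deposited, and 40081 and 28331 with a q of 0.05 or less. H3K27ac had 64460 and 76425 as deposited, but 27379 and 23861 with a q of 0.05 or less, so its direction depended on the q limit. The lists overlapped widely, with 59.5% (59.02 to 59.98%) of control H2A.Zac and 71.9% (71.3 to 72.4%) of control H3K27ac regions found with overexpression at that q.

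**Figure D3:**
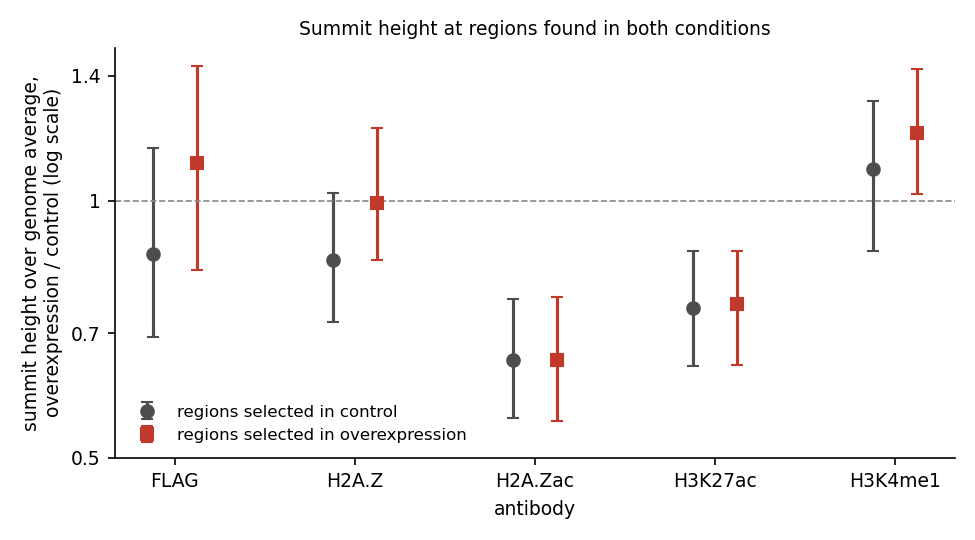
Ratio of summit heights, each over the genome average of its library, overexpression over control (log scale), at regions found in both conditions for each antibody. Points are medians and bars the quartiles over regions, with regions of a q of 0.05 or less selected in the control (circles) or with overexpression (squares); H2A.Zac and H3K27ac medians lie between 0.652 and 0.757 by either selection.

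H3K4me1, a mark of enhancers and promoter flanks, covered more of the genome with overexpression. Peak names of the control library spell another mark, H3k3me1, whereas its title and antibody label, followed here, say H3K4me1. The mark had 124449 regions in the control and 155160 with overexpression, a ratio of 1.247, and 20108 and 85651 with a q of 0.05 or less, a ratio of 4.26. These covered 14.7 and 76.2 Mb. At 5 limits on height over the genome average, which are relative to depth but fall on whole reads, the ratio was lower, 1.11 to 2.25. With that q the ratio was above 1 on each of the 41 chromosome arms with a value, from 2.80 to 9.07. The arms are not separate evidence, as a difference between whole libraries acts on all of them. For each other antibody the ratio was below 1 on every arm with a value. The strongest control region, at 20q13.33 (chromosome 20, 60928073 to 60930660), had a fold of 11.7 in the control and 10.1 with overexpression, and the next, at 11q13.3 (chromosome 11, 69256284 to 69260178), had 9.15 and 11.3. Of the 6 strongest control regions, 4 had the higher fold with overexpression, as did all 6 of the strongest overexpression regions. The strongest overexpression region with no control peak lay at 7q34 (chromosome 7, 139950766 to 139952684; fold 9.01, 28 reads). Most control regions were found again, 81.2% (80.7 to 81.8%), whereas 17.9% (17.7 to 18.2%) of the overexpression regions had a control region of that q. Of the overexpression regions, 38375 had no control H3K4me1 peak of any q, and 15.9% (15.5 to 16.3%) of these lay on control H2A.Zac, against 2.24% for random places. On H2A.Zac of overexpression, a shorter list, lay 9.64% (9.35 to 9.94%), against 1.45% for random places. Those with a control H3K4me1 peak lay on control H2A.Zac more often, in 29.7% (29.3 to 30.1%) of cases. At regions found in both, the median height ratio was 1.09 by the control list and 1.1996 by the overexpression list. The recovered depths of the H3K4me1 libraries differed by a ratio of 0.962, but the genome average, the mean number of extended reads over a base pair, by one of 1.146. The shortest peak, taken as the length of an extended read, was 255 bp with overexpression and 214 bp in the control. The higher average thus came from longer extended reads and not from more reads. With the overexpression reads at each summit thinned to the control average, the ratio of regions was 1.46 with at least 10 reads, 2.197 with 15 and 2.71 with 20, against 1.98, 3.54 and 4.89 before. A summit that would move by thinning is undercounted, so the thinned ratios may be too low.

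Combinations of marks followed H3K4me1. Its list was much longer with overexpression at this limit and the others shorter, which pushes the counts this way by itself. How far list length alone accounts for them was not computed. At a q of 0.05 or less, over 114142 places with at least 1 histone mark in either condition, all 8 combinations with H3K4me1 were found at more places with overexpression, by ratios of 1.44 to 7.08, and the 7 without it at fewer, by ratios of 0.200 to 0.5996. H3K4me1 alone was found at 8779 places in the control and 62116 with overexpression. H2A.Z with H2A.Zac and H3K27ac but no H3K4me1 was found at 8277 and 3662 places, and H2A.Z alone at 7275 and 1454. All 4 marks together were found at 1574 and 2950 places, of which 638 were in both conditions, although the lists of the other 3 marks were shorter with overexpression at that q. H2A.Z regions carried H2A.Zac in 69.9% (69.4 to 70.5%) of cases in the control and 82.8% (82.2 to 83.4%) with overexpression, where the H2A.Z list was shorter. H2A.Zac regions carried H2A.Z in 41.9% (41.5 to 42.4%) and 38.8% (38.3 to 39.4%).

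FLAG and H2A.Z lay together more often than random places did, at a minority of FLAG regions. As deposited, 13.6% (13.4 to 13.7%) of control FLAG regions overlapped H2A.Z, against 5.69% for random places, and 2.30% (2.26 to 2.34%) did with overexpression, against 1.498%. These were, at a q of 0.05 or less, 8.31% (8.10 to 8.52%) and 5.43% (5.23 to 5.64%), against 1.57% and 0.795%. H2A.Zac was found at 10.4% of such control FLAG regions, H3K27ac at 5.48% and H3K4me1 at 2.43%, against 2.74, 2.00 and 1.18% for random places. With overexpression these were 7.81, 4.73 and 7.98%, against 1.75, 1.66 and 4.83%. FLAG regions of the control that had a deposited overexpression peak carried control H2A.Z in 9.79% (9.53 to 10.1%) of cases, those of the control alone in 5.10% (4.81 to 5.40%), and those of overexpression alone in 2.80% (2.52 to 3.11%). H2A.Z of overexpression was found less often in each class, at 6.38% (6.17 to 6.61%), 3.204% (2.98 to 3.45%) and 1.68% (1.47 to 1.93%), but random places fell too, from 1.69, 1.255 and 1.21% to 0.895, 0.659 and 0.643%, as the H2A.Z list was shorter. Control H2A.Z regions with FLAG had a deposited H2A.Z peak with overexpression in 79.7% (78.6 to 80.7%) of cases and those without FLAG in 55.1% (54.5 to 55.8%). The order was the same within each of 5 classes of H2A.Z strength, from 52.2 against 30.7% in the weakest to 97.7 against 92.0% in the strongest. With 3 classes of region width in each, the regions with FLAG were found more often in 15 of 15 classes, in 10 of them beyond the intervals. By FLAG of overexpression this was 14 and 5 of the 15. Over all control regions the order was the same for H2A.Zac (86.3 against 71.4%) and H3K27ac (91.9 against 83.3%). Within classes of strength these differences shrank. H2A.Zac had 32.5 against 26.8% in the weakest class and 100% for both in the strongest. H3K27ac had 54.2 against 49.5% in the weakest, with overlapping intervals. In its next classes it had 77.5 against 77.2%, 94.99 against 95.5% and 99.77 against 99.81%, and in the strongest 100% for both. The H3K27ac order therefore did not hold at like strength. For H3K4me1 the order over all control regions was the other way, 87.8% (86.1 to 89.3%) with FLAG and 89.8% (89.4 to 90.3%) without.

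Segments of chromosomes 11 and 14 had a high local background in both conditions and held part of the strongest histone regions. At 11q13.2 the background behind the histone peaks was 4.16 times the genome average in the control and 4.38 times with overexpression, and at 31 to 33 Mb of 14q12 it was 2.94 to 4.19 times. Of the 100 strongest H2A.Z regions by q, 39 in the control and 32 with overexpression lay in 21 bins of these chromosomes, which make up 0.346% of the genome, and over the 8 histone lists 21 to 40 did. Ranked by fold, which divides by the local background, 0 to 4 did. A further 14 bins elsewhere were raised, of which 5 lay on 1q, and the one at 8q21.2, with 6.16 and 6.02 times, was the highest of the raised bins in both conditions. At 1q21.3, the band of VPS72, the background was 1.197 and 1.098, against medians of 1.16 and 1.098 over all bins. With a q of 0.05 or less, the ratio of H3K4me1 regions was 4.70 at 1q21.3, 3.38 at 1q32.3, the band of ATF3, 2.70 at 1p36.22, the band of MTOR, and 2.79 at 17p11.2, the band of SREBF1, against 4.26 in the whole genome. For H2A.Z the ratios in these bands were 0.516, 0.638, 0.628 and 0.490, against 0.541. Gene promoters were not analysed here.

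**Figure D4:**
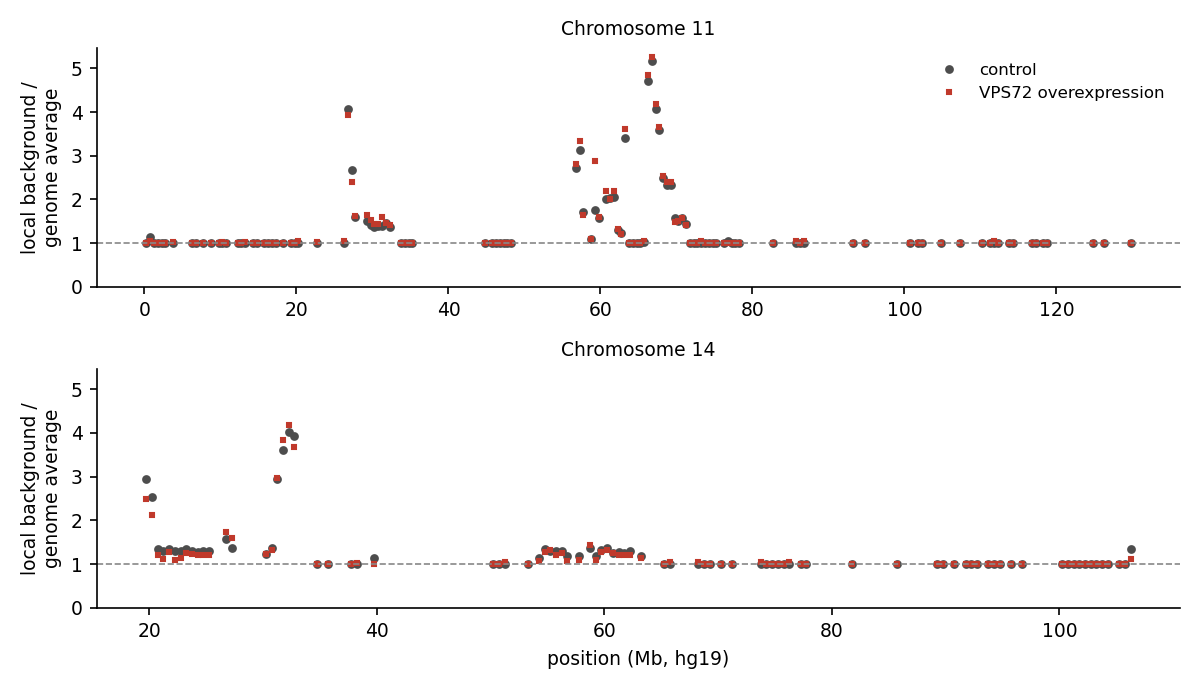
Local background behind the histone peaks over the genome average, per 500 kb bin with at least 50 peaks in each condition, along chromosomes 11 and 14 (position in Mb, hg19) in the control (circles) and with overexpression (squares). Both conditions peak together at 66 to 68 Mb of chromosome 11 and at 31 to 33 Mb of chromosome 14; values under 1 cannot appear, because the background of the peak caller has the genome average as its minimum.

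The inputs held few peaks, 467 in the control and 490 with overexpression, of which 16 and 18 had a q of 0.05 or less. The strongest lay next to centromeres, at 8p11.1 (chromosome 8, 43793843 to 43794039; folds of 2.19 and 2.15), Xq11.1 (chromosome X, 61687316 to 61687525; 1.68 and 1.93), 16q11.2 (chromosome 16, 46403574 to 46403786; 1.64 and 1.59) and 5q11.1 (chromosome 5, 49437235 to 49437430; 2.07 in the control). Input peaks overlapped 0.0163 to 0.0587% of the regions of the ChIP lists.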

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

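Chosen only after the result was seen were the calculation with random reads and the tests of single-read calls, of the p limit for H2A.Z (by reads and by heights) and for H3K4me1, of coverage, of where H2A.Z was lost and of a change of background brought by overexpression. The tests of height at shared regions and of raised parts of segments were fixed before their results were seen.

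The H3K4me1 list was longer with overexpression, with a ratio of 1.247, and the H2A.Z list shorter, with a ratio of 0.318, so that the marks went opposite ways. Reads placed at random at the recovered depths gave 1.02 to 1.101 and 0.145 to 0.179. These calls hold no enriched regions, for H2A.Z 60642 to 163188 in the control and 8802 to 29214 with overexpression. Reads were scaled and rounded down as fitted for each library, so H2A.Z needed at least 5 reads with overexpression and 4 in the control. The ratio of random calls is therefore not one of depth alone, nor of lists that hold enriched regions. With 1 library each, the difference between the marks was not tested.

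Peaks on GL000220.1, an unplaced contig with ribosomal RNA gene copies, lie outside the regions compared, and with a q of 0.05 or less the inputs had 0 kb there. FLAG peaks covered 57.4 kb in the control and 56.2 kb with overexpression, H2A.Z 20.3 and 10.95 kb, H2A.Zac 14.6 and 7.95 kb, H3K27ac 4.43 and 3.29 kb, and H3K4me1 3.598 and 11.7 kb. On the decoy sequence, which collects reads with no place on the chromosomes, 9 of the ChIP libraries had more peaks of that q than either input (110 and 95). They numbered 1457 and 903 for FLAG, 691 and 358 for H2A.Z, 235 and 218 for H2A.Zac, 141 and 165 for H3K27ac, and 230 for H3K4me1 with overexpression.

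The deposited FLAG list was longer with overexpression, with a ratio of 3.00. A candidate explanation is single-read calls in a shallower library. Without the 297013 overexpression peaks of 1 read alone, that list would still be the longer one. With at least 3 reads at the summit the ratio was 0.909. Peaks of 2 reads, 101248 with overexpression and 15069 in the control, are dropped there too. This limit is stricter in the shallower overexpression library, which lowers the ratio by itself, so the value does not settle the explanation. Limits on height over the genome average were not counted for FLAG. In the overexpression library a lone read had a p of 0.0437 against the genome average, under the limit of 0.05, and in the deeper control library one of 0.0772. A stronger FLAG signal at places already bound cannot be told apart from an equal one, because the median height ratio at shared regions was 0.865 or 1.11 depending on which library selected them. More VPS72 binding after overexpression stays open as the biological explanation for regions found only there, and so does nonspecific FLAG signal.

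H3K4me1 was found at more regions and H2A.Z at fewer with overexpression. For H3K4me1 the values argue against the p limit acting on whole reads as the whole reason. The limit lies at 5 reads in both libraries, and the ratio was 1.98 with at least 10 reads. At 5 limits on height over the genome average, which also fall on whole reads, the ratio was 1.11 to 2.25. A difference in coverage cannot be told apart from a true gain. The genome average was 1.146 times higher with overexpression, although the recovered depth was 0.962 times that of the control. This came from longer extended reads, taken as 255 bp with overexpression and 214 bp in the control, and not from more reads. With reads thinned to the same genome average, the ratio with at least 10 reads fell to 1.46. This was short of the 1.5 set as the bound against coverage, though the ratio was 2.197 with 15 and 2.71 with 20. Thinning kept each summit in place and undercounts regions whose summit would move, which lowers these ratios. Higher enrichment at places already called stays open, as the lower of its median height ratios was 1.09, and capture and biology were not separated. For H2A.Z the effect of the p limit cannot be told apart from a true loss. With at least 10 reads the ratio was 1.11, but 10 reads is a lower height with overexpression, where the genome average was higher. At 5 limits on height over the genome average it was 0.386 to 0.758. These also fall on whole reads, at unlike heights in each library for some limits. At limits of 4 and 8 the heights were nearly equal, and the ratio was 0.407 and 0.679. Fewer H2A.Z summits were thus counted at like height, in 1 library per condition, and capture and biology were not separated. Random reads, which form no enriched regions, gave a ratio further below 1 than the lists did, after scaling and rounding that differed between the libraries. Of the control H2A.Z regions not found again, 88.7% (88.1 to 89.3%) had no FLAG region, against 78.1% of all control H2A.Z regions. Most therefore lay outside called FLAG regions. This cannot decide whether a loss of H2A.Z went with FLAG, because few regions carried a FLAG call at all. FLAG was also called more often at strong regions, at 2035 of 5220 in the strongest class against 655 of 5220 in the weakest. Strong regions were found again more often. Some loss at FLAG regions is not excluded, as 79.7% of the control H2A.Z regions with FLAG were found again. A wrong label of the control H3K4me1 library, whose peak names spell another mark, had no test of its own; with a q of 0.05 or less, 81.2% of its regions overlapped H3K4me1 of overexpression and 30.5% control H3K27ac. A wider effect of overexpression on both marks stays untested, because the condition has 1 library per mark.

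Segments of chromosomes 11 and 14 had a high background and held part of the strongest histone regions, 21 to 40 of the 100 strongest by q in each histone list; 14 bins elsewhere were raised too. A change brought by overexpression is argued against, as 95.5% of the bins of these chromosomes raised with overexpression, 21 of 22, were raised in the control too, and the other had 1.76 times the genome average there. Extra copies of these segments and reads piled up on collapsed repeats cannot be told apart. A median of 100% of the 50 kb parts of the raised bins were raised, but the bins had been picked at a higher limit than their parts, and 6 raised bins near centromeres, where repeats are common, had a median of 90%; 4 of these lie on chromosomes 11 and 14. No DNA measurement used here shows the copy number directly.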

How the results depend on the processing

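Limits on q of 0.05, on reads and on heights were chosen after the data were seen, and the other alternatives before. The values given are those that changed direction or moved by more than 1.5 times (ratios) or out of the 95% interval (percentages), and with 1 library per group no alternative could leave out a replicate. No paired analysis was possible because no result comes from a test. Of 59 alternatives for ratios of region numbers, 30 stayed within 1.5 times in the same direction. Among them were every count of deposited lines, which joining left the same. Every count without input regions was another, and this dropped at most 0.0587% of a list. Limits of 3 reads for the histone marks, and of 4 for H2A.Z, dropped almost nothing, as their peaks began at 4 or 5 reads. Such settings could hardly move a ratio, so the 30 are no measure of robustness. H2A.Zac stayed within 1.5 times in all of its alternatives. For FLAG the ratio was 0.909 without peaks of 1 or 2 reads. This limit is stricter in the overexpression library, whose genome average was 0.329 reads against 0.456 in the control. Limits on height were not counted for FLAG. For the other antibodies the cause was not tested. The settings intended for promoters and gene lists were not run, for want of an annotation of the build used.

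With a q of 1e-05 or less the ratio was 0.587 for FLAG, 0.701 for H2A.Z, 0.760 for H3K27ac and 16.8 for H3K4me1. With a fold of at least 5 it was 0.683, 0.739, 0.748 and 4.69, and with a q of 0.05 or less 0.677, 0.541, 0.872 and 4.26. By covered length H3K4me1 had 1.95. With at least 3 reads FLAG had 0.909. With at least 10 reads the ratio was 0.480 for FLAG, 1.11 for H2A.Z, 0.965 for H3K27ac and 1.98 for H3K4me1. H2A.Z was counted at 10 limits on reads, of which 6 gave a ratio under 1 and 4 above. Those of at least 3 and 4 reads left both lists almost whole. Beyond those within 1.5 times it had 0.685 with at least 7 reads, 0.921 with 8, 1.18 with 12, 1.2502 with 15 and 1.29 with 20. Limits on reads or on q do not allow for depth, which with overexpression was higher for H2A.Z and lower for FLAG. Height limits allow for it only in part, as they fall on whole reads. At heights over the genome average of at least 6, 8 and 10, H2A.Z had 0.758, 0.679 and 0.534, and its ratio was under 1 at all 5 heights tried. H3K4me1 had 3.54 with at least 15 reads, and 2.15 and 2.25 at heights of at least 8 and 10; over the 5 heights it ranged from 1.11 to 2.25.

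The percentage of control regions found with overexpression stood at 44.3% for FLAG, 15.1% for H2A.Z, 40.4% for H2A.Zac, 44.2% for H3K27ac and 58.4% for H3K4me1 as deposited. By reciprocal overlap of 50% it was 26.3, 7.76, 28.9, 30.9 and 18.5%, and with the summit inside 34.3, 10.9, 36.0, 39.1 and 48.9%. With a q of 1e-05 or less it was 48.5, 33.3, 59.3, 72.2 and 85.5%, with equal numbers 34.8, 34.8, 43.7, 43.0 and 54.0%, and with a q of 0.05 or less 40.2, 37.3, 59.5, 71.9 and 81.2%. FLAG regions with H2A.Z, in the control and with overexpression, were 4.31 and 0.772% by reciprocal overlap, 7.83 and 1.36% by summit, 2.92 and 1.63% with a q of 1e-05 or less, 12.7 and 10.1% with equal numbers of 57951 regions, and 8.31 and 5.43% with a q of 0.05 or less. The control percentage was the higher one under each, also with equal numbers. Set over random places, which allows for the length of the H2A.Z list, the order depended on the limit. It was 2.38 times in the control and 1.54 with overexpression as deposited, and 5.30 and 6.83 times with a q of 0.05 or less, the opposite order. Leaving out input regions kept all 7 percentages within their intervals. In the FLAG libraries the genome average was 0.456 reads in the control, where 2 reads pass the p limit, and 0.329 with overexpression, where 1 does.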

Other observations

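FLAG regions with a q of 0.05 or less stood apart from the histone marks in their place on the chromosomes. With a q of 0.05 or less, 5.97% (5.80 to 6.15%) of control FLAG regions and 5.96% (5.75 to 6.18%) of overexpression ones lay within 1 Mb of a chromosome end, a stretch that makes up 1.35% of the genome. For the histone lists this was 1.86 to 3.08%. Unstained bands, which are rich in genes, held 66.0% of control and 63.9% of overexpression FLAG regions, against 42.4% of the genome and 55.3 to 59.0% of the histone regions. As deposited this held for the control FLAG list (4.00% near ends and 60.9% in unstained bands) but not for that of overexpression (1.78 and 45.9%), against 1.74 to 2.30% and 48.5 to 55.4% for the histone lists. The 1000 strongest FLAG regions carried any of the 4 histone marks in 15% (12.9 to 17.3%) of cases in the control and 14.4% (12.4 to 16.7%) with overexpression, against 6.75% and 8.48% for random places. H3K27ac lay at 2.90% (2.03 to 4.13%) of the strongest 1000 control FLAG regions, with a random value of 3.02%, and at 7.15% (6.80 to 7.51%) of those ranked 20001 to 40000, with a random value of 1.99%. These values were computed after the data were seen.

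Overlap among the strongest regions differed between antibodies. Of the 2000 strongest control regions, 54.9% (52.7 to 57.0%) were among the 2000 strongest with overexpression for FLAG, 34.8% (32.7 to 36.9%) for H2A.Z, 62.4% (60.3 to 64.5%) for H2A.Zac, 74.8% (72.8 to 76.6%) for H3K27ac and 35.9% (33.8 to 38.0%) for H3K4me1. In the whole overexpression lists, 97.5 to 100% of them were found.

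Reads placed at random at each library's recovered depth and called at a p of 0.05 gave region ratios, overexpression over control, of 2.58 to 3.56 for FLAG, where the deposited lists had 3.00. For H2A.Z they gave 0.145 to 0.179, where the lists had 0.318, for H2A.Zac 1.24 to 1.31 (0.913), for H3K27ac 1.56 to 1.68 (1.19) and for H3K4me1 1.02 to 1.101 (1.247). The calculation assumes evenly spread reads with no enriched regions, the scale fitted to each library, the assumed genome size and 3 settings for joining calls.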
